A study of Drosophila melanogaster with 2 samples.

How the data were processed

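Chromatin immunoprecipitation followed by sequencing was performed on whole Drosophila melanogaster embryos of 0 to 18 hours that carried a transgene for lame duck (lmd) fused to eGFP, a green fluorescent protein, and the fusion protein was precipitated with an antibody against GFP. There were 2 samples, which the labels name as biological replicates 1 and 2, and both belong to 1 group. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. Because the labels give no second group, no difference between conditions was computed. The control libraries to which the labels point were not analysed here.

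Only peak lists were used, in coordinates of the assembly dm6, per the labels. The aligner, the peak caller and their versions are not given in the sources used here. The deposited lists fall into 3 kinds: a thresholded set and a ranked list for each replicate alone, a conservative and a wider thresholded set for the peaks called on both replicates together, and the ranked lists behind these. The listing deposited with the files names, as sources of each list, the alignments of 1 or both replicates and a control file. It also names a further source file whose role it does not give.

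The signal value of each peak is the value that the authors' peak caller gave it, with no normalization stated in the deposited files. It was used to rank, divide or describe peaks within 1 list, and between lists only for the correlation of matched peaks of the replicates (Spearman, and Pearson on log10 values). The score of each peak in the deposited thresholded sets was a whole number from 830 to 1000, and in the ranked lists it followed the IDR, the irreproducible discovery rate, which measures how repeatable the rank of a peak is between 2 lists. A score of 830 corresponds to a global IDR of about 0.01, so the authors' thresholded sets were kept at that level. The deposited ranked lists also carry the −log10 of the global IDR, capped at 5, and stricter and looser sets were taken from it. The 16 further columns of the ranked lists of both replicates together were not used. The number of reads per sample is not in the files used here, so read depth is unknown, and it limits which weak peaks could be called.

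Peaks on the 6 main chromosome arms (2L, 2R, 3L, 3R, 4 and X) were analysed, and the conservative set was the main set. Each peak was placed by its summit. The genome was Release 6 and genes were taken from annotation release 115, whose arm names and lengths were compared with the positions in the files. A promoter summit lay within 500 bp of a transcription start site (TSS) of a protein-coding gene. Other summits were assigned in the order 5′ UTR, coding sequence, 3′ UTR, intron and outside protein-coding genes. The locus of a gene was its body with 2 kb on each side. Neither rule shows which gene a site regulates.

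Replicate sets were compared by overlap of at least 1 bp against 1000 circular shifts of the other set within each arm (200 for ranked lists and for the conservative set), with a one-sided permutation p. Genomic classes were tested against 1000 circular shifts of the summits with two-sided permutation p-values. The 18 gene lists were those for myoblast fusion, mesoderm and muscle transcription factors, sarcomere, muscle attachment, visceral mesoderm, neurons, neural progenitors, glia, epidermis, trachea, hemocytes and fat body, endoderm and gut, germ line, segmentation and Hox, hedgehog and wnt, Notch with EGFR and FGF, heat shock, and cytoplasmic ribosomal proteins. Each was compared with 10000 random lists matched on deciles of locus length, with two-sided permutation p-values. Motifs and all words of 7 bases (reverse complements merged) were counted within 100 bp of the summit and in an equally wide window 1000 bp to the lower-coordinate side of the same summit. The counts were compared with an exact McNemar test. Fisher's exact test compared the 1250 peaks of highest signal with the 1249 of lowest signal, the ends of a division into 4 equal parts. Adjusted p-values follow Benjamini and Hochberg within each family of tests, and 0.05 was the threshold. Shares carry Wilson 95% intervals and densities exact Poisson 95% intervals. Peaks are not replicates: p-values and intervals computed over peaks or genes cover counting error only, and with 2 samples of 1 group no spread between animals enters them.

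The tests, the gene lists, the motifs and a first set of alternatives were fixed before the data were examined. So was the rule for named genes: the 20 peaks with the highest signal, each with the gene of the nearest TSS; lmd, Mef2 and sns in every case; in each list up to 4 members with the highest-signal peak in the locus; the 10 genes with the most summits; all fixed motifs; and the 10 words of 7 bases with the smallest p. The result of 1 gene that the rule takes is not reported here. Genes named outside this rule were chosen after their values were seen, as were the words containing CACTG and their positions, the peaks nearest to lmd, the single Mef2 peaks and the counts at the own TSS of list genes. The position test counted words within 150 bp of the summit, on the strand of the word.

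Alternatives were the other peak sets, each replicate without the other, the peaks of higher signal, stricter and looser IDR levels, overlap of 50% of each peak or of summits within 100 bp, uniform in place of shifted positions, promoter windows of 200 and 1000 bp, locus margins of 0 and 5 kb, nearest-TSS assignment, Fisher's exact test without length matching, flanks on the other side or 2000 bp away, shuffled sequence that keeps the dinucleotides, windows of 50 bp, peaks away from promoters, and words of 6 bases. Genomic windows matched on GC content, lists matched also on neighbouring genes, and the IDR levels of 0.001 and 0.05 were added after the data had been seen. The planned IDR of 0.01 turned out to equal the deposited threshold. The ranked list behind the conservative set held 5128 peaks at that level, against 5012 in the set. Why the set is smaller is not given in the sources used here.

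The procedures for overlap, genomic classes, gene lists, motifs and words were tested on simulated data; the comparison of peaks of highest and lowest signal, the word positions and the density ratio were not. Overlaps equalled a direct count for all 400 simulated peaks under each of the 3 overlap rules. On 5000 uniform summits, 0% of class tests passed. With hit genes drawn by length alone from the 13945 genes, 0.111% of list tests passed. When 80% of members were made hits, the fusion list of 22 genes passed in 20% of draws, the transcription factor list of 31 in 32%, the sarcomere list of 26 in 48% and the ribosomal list of 92 in 100%. Short lists were therefore tested with little power. Among the 8192 words of 7 bases, a planted word ranked 1, and 0 words passed when none was planted. Both sides of this simulation had the same base composition. It therefore could not show how many words pass because summits and flanks differ in GC content. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks on the Y chromosome and on unplaced sequences were left out of the tests because the annotation and the shifts were set up for the main arms, and their numbers are given in the closing section.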

Results

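Lame duck (lmd) is a zinc finger transcription factor of the Gli superfamily that fusion-competent myoblasts, the cells that fuse with founder cells to build larval muscles, need in order to differentiate. The samples were 2 biological replicates of whole embryos of 0 to 18 hours carrying lmd-eGFP, precipitated with anti-GFP, so muscle precursors were mixed with all other embryonic tissues. Peaks were called on each replicate alone and on both together. The conservative set held 5012 peaks, 4998 of them on the 6 main arms, with a median width of 364 bp and signal values from 2.02 to 4246 (median 159.7). The wider set from both replicates held 6406 peaks, the set of replicate 1 held 3983 and that of replicate 2 held 5551. The unthresholded ranked lists held 115082 and 90837 peaks. Signal values are the authors' and have no unit that allows their levels to be compared between lists, and read depth is unknown.

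The first comparison asked how far the replicates found the same sites. The sites of highest signal were shared and the weak ones were shared less often. In replicate 1, 3162 of 3929 peaks overlapped a peak of replicate 2, which is 80.5% (Wilson 95% interval 79.2 to 81.7). In replicate 2, 3185 of 5544 peaks overlapped one of replicate 1, which is 57.4% (56.1 to 58.7). Shifted peaks overlapped in 2.44% and 1.74%, and both permutation p-values were 0.001, the smallest that 1000 shifts can give. Among the tenth of peaks with the highest signal, 100% of replicate 1 peaks and 99.1% of replicate 2 peaks were shared. Among the tenth with the lowest signal these shares were 51.8% and 27.3%. Many unshared peaks lay below the threshold of the other replicate. Its unthresholded ranked list overlapped 97.8% of all replicate 1 peaks and 92.4% of all replicate 2 peaks, against 35.9% and 43.7% after shifts. All 20 peaks of highest signal in the conservative set, among them those at Ugalt, ph-p and Trl, were in both replicate sets. The authors kept the conservative set from a comparison of the replicates, so its strongest peaks were likely to be in both. Of all its main-arm peaks, 71.4% overlapped the replicate 1 set and 83.0% the replicate 2 set. Over 3080 matched peaks the signal values of the replicates had a Spearman rho of 0.692 and a Pearson r of 0.765 on log10 values, across peaks and not across samples, and the median distance between matched summits was 17 bp. In the ranked lists the rho was 0.419 over 57838 matched peaks. The larger replicate set was 1.39 times the smaller, and the larger joint set was 1.28 times the smaller.

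**Figure D1:**
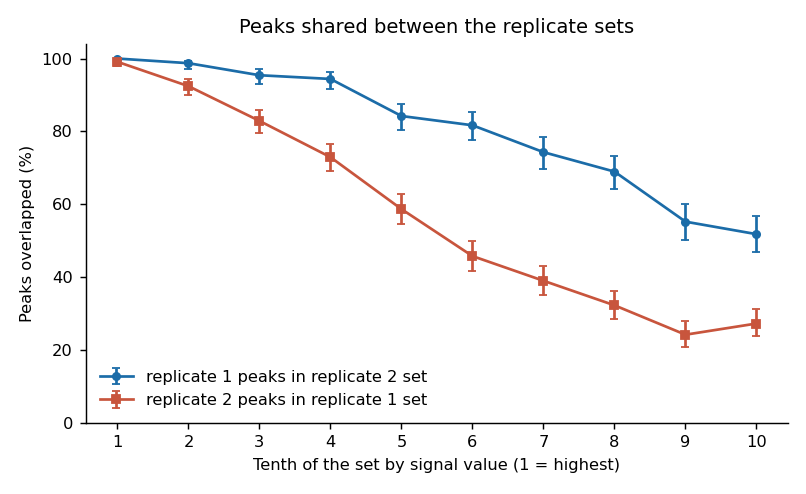
Share of peaks of each replicate set (percent, y axis) that overlapped a peak of the other replicate, for 10 equal parts of the set ordered by signal value (x axis, 1 = highest); bars are Wilson 95% intervals. The share fell from 100% to 51.8% in replicate 1 and from 99.1% to 27.3% in replicate 2.

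The 20 peaks of highest signal lay beside genes of varied function, and no gene of the fixed muscle lists was nearest to any of them. The first was at CG14100 on chromosome 3L (19590430 to 19590808), with a signal of 4246 and its summit 96 bp from the TSS. The second was at Ugalt, a Golgi transporter of UDP-galactose, on chromosome X (2703687 to 2704088), with a signal of 4195 and its summit 38 bp from the TSS. Genes of mitochondrial function were represented by mRpL41 (signal 3295, 141 bp from the TSS) and mRpS10 (2836, 126 bp), which encode proteins of the mitochondrial ribosome, and by PNPase (2651, 83 bp), an RNA-degrading enzyme. Chromatin genes were represented by the Polycomb-group gene ph-p (3026, 496 bp), by Chro (2650.2, 88 bp), which encodes a chromodomain protein, and by Trl, the gene of GAGA factor, whose peak lay in an intron 1539 bp from the TSS (signal 2358). The translation factor gene eIF6 had a peak of signal 2365 at 110 bp. Of the 20 peaks, 13 were at promoters, and the median distance to the nearest TSS was 134 bp. At 6 of them a TSS of another gene also lay within 500 bp, so the nearest gene is only 1 of those the site adjoins.

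Promoters and introns together held most summits, and coding exons held almost none. Promoters held 1910 of 4998 summits, 38.2% (Wilson 95% interval 36.9 to 39.6), against 11.4% of shifted summits, a ratio of 3.34. Coding sequence held 46 summits, 0.920% against 13.9%, and 3′ UTRs held 43, 0.860% against 4.55%. Regions outside protein-coding genes held 18.1% against 30.02%. These 4 differences had permutation p-values of 0.0020, the smallest that 1000 shifts can give two-sided (adjusted 0.0030). The 5′ UTRs held 0.460% against 0.795% (permutation p 0.014, adjusted 0.0168). Introns held 41.5% against 39.3% (permutation p 0.04, adjusted 0.04), but the direction of the intron difference turned in 4 alternatives, with replicate 2 alone giving 36.6%, and in replicate 1 alone it did not pass. Nor did it pass in the wider joint set, where introns held 39.5% against 39.3% (adjusted permutation p 0.927).

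**Figure D2:**
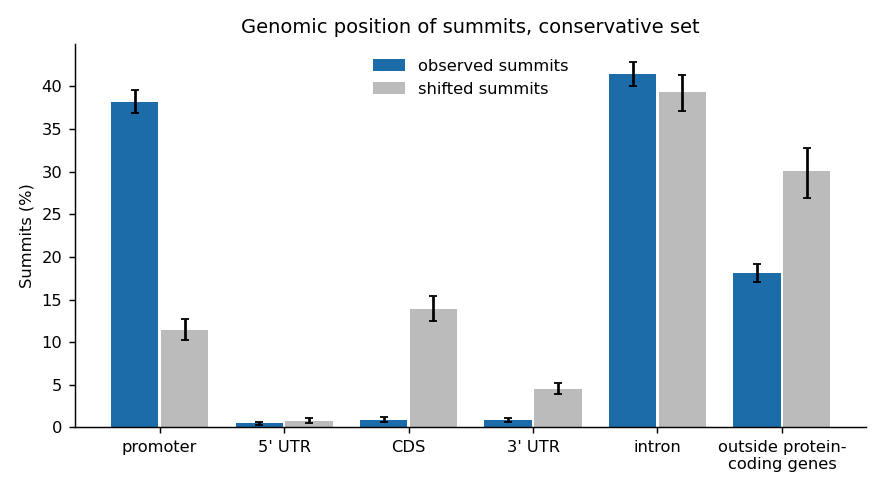
Percent of the 4998 conservative summits (y axis) in each genomic class (x axis), beside the mean of 1000 circular shifts; bars on the observed values are Wilson 95% intervals and bars on the shifted values span the central 95% of shifts. Promoters held 38.2% against 11.4%, and coding sequence 0.920% against 13.9%.

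The X chromosome carried more peaks per Mb than the large autosomal arms, and chromosome 4 carried almost none. The X had 44.9 peaks per Mb (exact Poisson 95% interval 42.2 to 47.7), while 2L, 2R, 3L and 3R had 38.1, 34.2, 37.7 and 34.8. The ratio of the X to these autosomal arms was 1.24 (95% interval 1.16 to 1.33), and it was 1.20 in each replicate set alone. The unthresholded lists showed no such excess, with 843 and 655 peaks per Mb on the X in replicates 1 and 2, inside the ranges of 777 to 909 and 649 to 722 on the large autosomal arms. Chromosome 4, a small and largely heterochromatic chromosome, had 2 peaks, or 1.48 per Mb (0.180 to 5.36), although the annotation places 59.3 protein-coding genes per Mb on it. In the unthresholded lists chromosome 4 had 21 and 28 peaks, 15.6 and 20.8 per Mb, against 649 to 909 per Mb on the other arms. The lack was thus present before any threshold, and these lists alone cannot show that binding is absent from chromosome 4.

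Of the genes central to the known role of lmd, Mef2 held several sites and sns held none. Mef2, the MADS-box factor of muscle differentiation on chromosome 2R (9913496 to 9958858, minus strand), had 7 summits in its locus. The strongest, at 9959705 to 9960103 with a signal of 1699.6 and rank 40 of all peaks, lay 1041 bp from the nearest Mef2 TSS but 167 bp from that of Pdrg1, and a TSS of Pal1 lay within 500 bp. Another (9942869 to 9943102, signal 441) was in the 5′ UTR of Mef2, and the other 5 were intronic with signals from 96.1 to 145. All 7 overlapped peaks of replicate 2, and 3 overlapped peaks of replicate 1. The adhesion gene sns of fusion-competent myoblasts (2R, 8798489 to 8856091) had 0 summits in every set. The nearest conservative summit lay 51403 bp from the gene and that of replicate 1 alone 51352 bp, while the wider joint set had one at 4177 bp (signal 70.6) and replicate 2 alone at 4166 bp (55.1). The lmd gene itself (3R, 23021222 to 23026713, minus strand) had 0 summits within its locus, but a peak at 23028616 to 23028836 (signal 548, rank 409) had its summit 2011 bp beyond the 5′ end, 11 bp outside the locus. Replicate 1 alone placed that summit at 1969 bp, inside the locus.

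None of the 5 gene lists for muscle passed the test against random genes of like length, with 3 lists above and 2 below their matched means. In the list for myoblast fusion, 15 of 22 genes had a summit against a mean of 10.7 in matched lists (permutation p 0.086, adjusted 0.469 over 18 lists). Its members with the strongest peaks were kirre, the founder cell adhesion gene (32 summits, highest signal 491, in an intron), Hem, of the SCAR actin complex (453, 327 bp from its TSS and nearer to IleRS), mbc, which activates Rac (434, 186 bp from its TSS and nearer to Nup98-96), and Rac1 (298, in the 3′ UTR of the neighbour scf). The kirre summit of signal 491 also lay within CG32795, nearer to its TSS than to that of kirre, 45981 bp away. Of the transcription factors of mesoderm and muscle, 13 of 31 had a summit against 15.2 (permutation p 0.533, adjusted 0.737), led after Mef2 by the T-box gene org-1 (965, 353 bp from the TSS), the zinc finger gene zfh1 (687, intron) and the paired-domain gene Poxm (564, 423 bp). Of the sarcomere genes, 10 of 26 had one against 11.6 (permutation p 0.655, adjusted 0.737), led by the titin-like sls (531, 270 bp from its TSS), Zasp66 of the Z-disc (305, intron), the myosin light chain gene Mlc2 (231, at the promoter of Rsod) and Actn (227, at the promoter of usp). Muscle attachment genes had 12 of 18 against 9.85 (permutation p 0.415, adjusted 0.679), with the strongest peaks at stck (731), the tendon regulator sr (636) and the talin gene rhea (441). Visceral mesoderm genes had 8 of 12 against 5.96 (permutation p 0.345, adjusted 0.679), with bin at 469. When matching on gene length was left out, 5 of the 18 lists passed Fisher's exact test: fusion (adjusted p 0.0064), muscle attachment (0.0215), hedgehog and wnt (0.0337), Notch with EGFR and FGF (7.0e-04) and the ribosomal list. The fusion list passed in no other alternative (adjusted p 0.124 to 0.983).

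Cytoplasmic ribosomal proteins were the 1 list of 18 that passed the threshold against its matched lists. A summit lay in the locus of 60 of the 92 genes of the cytoplasmic ribosome, 65.2%, against a mean of 23.1 genes in matched lists (permutation p 2.0e-04, the smallest that 10000 lists can give; adjusted 0.0036). Over all 13945 protein-coding genes the share with a summit was 33.5%. Within 500 bp of the gene's own TSS there was a summit at 52 of the 92, 56.5%, against 17.2% of all protein-coding genes. Peaks at RpL32 (619), RpS27 (608) and RpL7 (523) had summits 158, 34 and 37 bp from the TSS of the gene. The stronger of 2 peaks in the RpL3 locus (909.8) lay 4782 bp from the TSS of that gene, at the promoter of the neighbour CG17726.

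Signalling genes and markers of other tissues gave values on both sides of their matched lists. In the Notch, EGFR and FGF list 16 of 21 genes had a summit against 11.04 (permutation p 0.0302, adjusted 0.272), among them aos, which encodes an EGFR antagonist (919.7, intron), the EGFR ligand gene spi (805, 191 bp from the TSS), the Notch coactivator gene mam (12 summits, 782) and E(spl)m8-HLH, whose peak (879) lay at the promoter of gro. Hedgehog and wnt genes had 11 of 17 against 8.78 (permutation p 0.396, adjusted 0.679), with the receptor gene fz at 479. Heat shock genes had 7 of 15 against 4.71 (permutation p 0.321, adjusted 0.679), and Hsp23 and Hsp27 shared a peak of 1390.2 that lay 153 bp from the Hsp27 TSS. Neuronal genes had 8 of 16 against 9.40 (permutation p 0.638, adjusted 0.737), with elav at 1295 and 263 bp from its TSS. Glial genes had 6 of 10 against 4.54 (permutation p 0.528, adjusted 0.737), with moody, a receptor gene of the blood-brain barrier, at 1210.3. Neural progenitor genes had 4 of 18 against 7.56 (permutation p 0.104, adjusted 0.469), with numb at 769. Epidermal genes had 7 of 17 against 8.44 (permutation p 0.619, adjusted 0.737), with grh at 399, and tracheal genes 6 of 13 against 6.75 (permutation p 0.885, adjusted 0.898), with rib at 255. Hemocyte and fat body genes had 5 of 15 against 7.30 (permutation p 0.326, adjusted 0.679), with ush at 305. Genes of the endoderm and gut list had 2 of 9 against 4.67 (permutation p 0.135, adjusted 0.475), namely otp at 719 and NK7.1 at 369. Germ line genes had 5 of 17 against 5.77 (permutation p 0.898, adjusted 0.898), with piwi at 393. Segmentation and Hox genes had 7 of 24 against 10.8 (permutation p 0.158, adjusted 0.475), with Antp at 292. In replicate 2 alone the segmentation and Hox list was lower than its matched lists, at 16.7% of genes (adjusted permutation p 0.0072, against 0.158 to 1 in its other alternatives).

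**Figure D3:**
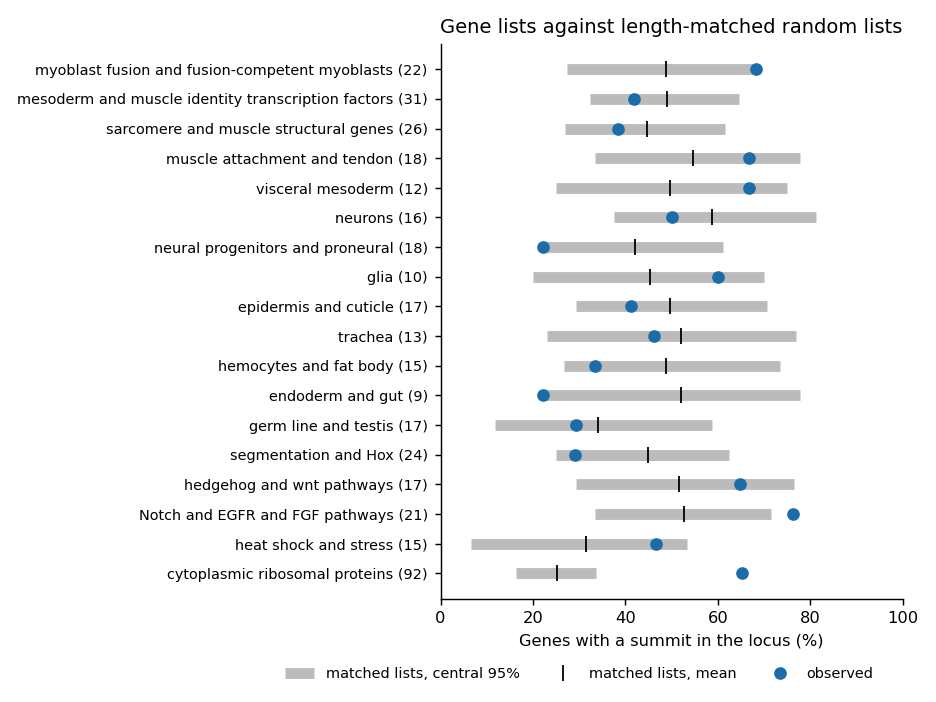
Percent of genes in each fixed list (y axis, number of genes in parentheses) with a summit in the locus (x axis, points), beside the mean (tick) and central 95% (grey bar) of 10000 length-matched random lists. The ribosomal list lies at 65.2% and its matched mean at 25.2%.

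When the question was limited to the 1250 peaks with the highest signal, from 273 upward, no list passed the threshold. Ribosomal protein genes had 19 of 92 members with such a peak against 8.87 (permutation p 0.0028, adjusted 0.0504). Notch, EGFR and FGF genes had 9 of 21 against 4.63 (permutation p 0.048, adjusted 0.404), the myoblast fusion list had 4 of 22 against 4.42 (permutation p 1, adjusted 1), and tracheal genes had 0 of 13 against 2.83 (permutation p 0.078, adjusted 0.404). The ribosomal and the Notch, EGFR and FGF lists were the only ones with an unadjusted permutation p below 0.05.

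The genes with the most summits included signalling and transcription factor genes. The gene with the most was kirre, with 32 over 394149 bp, followed by CG1677 with 20, by shn, a zinc finger gene of the Dpp pathway, and sbb with 14 each, by the nuclear receptor gene Hr4 and the forkhead gene CHES-1-like with 13 each, by mam and the kinase gene Raf with 12 each, and by Ptp61F and Tlk with 11 each. Per kb of locus, CHES-1-like had 0.419 summits and kirre 0.0804. The strongest peak of each of these 10 genes was in both replicate sets, with signals from 412 at Ptp61F to 1448 at Tlk. The conservative set favours such peaks, because the authors kept it from a comparison of the replicates. At kirre, CG1677, mam and Ptp61F the strongest peak was nearest to a TSS of another gene, namely CG32795, CBP, CG18371 and ru. No test was applied to single genes.

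Motif counts asked whether sequences known for factors of this family and of mesoderm marked the summits. The zinc finger cores were rarer at summits than 1000 bp away. The Gli-type core CCACCCA was within 100 bp of 2.26% of summits against 3.58% of flanks (ratio 0.631, adjusted p 1.7e-04), the Zic-type core CCCGCTG of 1.08% against 2.32% (0.466, 9.0e-06) and the run CCCCCC of 3.44% against 5.36% (0.642, 1.1e-05). The GAGA factor word was also rarer, at 2.68% against 3.64% (adjusted p 0.0123). Motifs of Mef2 (12.5% against 7.06%, adjusted p 1.5e-18), of homeodomains (18.4% against 12.2%, 9.4e-17) and of Tinman (8.74% against 6.58%, 1.2e-04) were more frequent at summits, and so were GATA (13.99% against 11.2%, 7.6e-05) and FoxF (13.7% against 12.1%, 0.0175). The promoter word of DREF, TATCGATA, was at 2.36% of summits against 0.380% (6.21 times, adjusted p 9.6e-18), and that of M1BP at 1.28% against 0.600% (9.1e-04). Twist-type E-boxes (adjusted p 0.282), Zelda (0.914), Grainyhead (0.133), Ets (0.05004) and Suppressor of Hairless (0.888) did not pass in the exact McNemar tests over 16 motifs. Against flanks, M1BP passed in replicate 2 alone (ratio 3.68) but not in replicate 1 alone (1.64, adjusted p 0.0854), GAGA factor did not pass in replicate 2 alone (0.852, 0.184), and Ets was rarer at summits in replicate 1 alone (0.478, 0.0078) and in replicate 2 alone (0.587, 0.0175).

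Several of these directions depended on the background. Summit windows had 35.6% GC and flanks 42.4%. Against genomic windows of equal GC content the Gli-type core gave a ratio of 1.15 (adjusted p 0.51) and the Zic-type core 1.29 (0.438), while CCCCCC (1.48, adjusted p 0.0038), GAGA factor (1.56, 0.0038) and the Twist-type E-box (1.13, 0.0452) were more frequent at summits. Against these windows Mef2 (1.18, adjusted p 0.0074), Tinman (1.24, 0.0052), DREF (2.74, 3.6e-08) and M1BP (2.46, 5.0e-04) were again more frequent, and homeodomain (1.02, 0.789), GATA (0.961, 0.637) and FoxF (1.03, 0.69) did not pass.

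**Figure D4:**
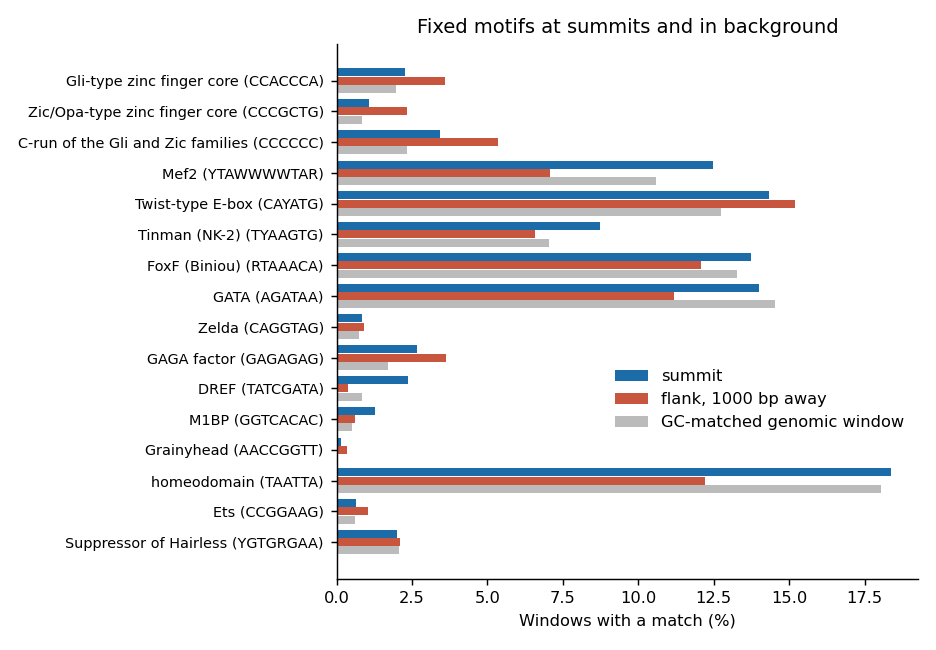
Percent of windows within 100 bp of the 4998 conservative summits, and of the background windows, that hold each fixed motif. The Gli-type core is at 2.26% of summits, 3.58% of flanks and 1.961% of GC-matched windows, while DREF is at 2.36%, 0.380% and 0.860%.

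A search of all 8192 words of 7 bases found 1253 more frequent and 2592 less frequent at summits than in flanks. Of the 10 words with the smallest p, 9 held only A and T, led by TTTAAAA (24.0% of summits against 10.2% of flanks, adjusted p 6.9e-73). The other was CAGTGTA, at 8.18% against 1.68% (adjusted p 8.7e-52). Against GC-matched windows 428 words were more frequent, and 9 of the first 10 contained CACTG or its complement, with ACAGTGG at 9.70% against 1.88%, CAGTGCA at 10.6% against 2.54% and CACTGAG at 7.08% against 1.26% of windows. The 5 bases CACTG alone lay at 50.4% of summits, 30.8% of flanks and 22.9% of GC-matched windows, at 54.3% of summits away from promoters and at 43.9% of promoter summits. TATCGATA belonged to promoters, at 5.50% of promoter summits against 0.419% of their flanks and 0.421% of other summits against 0.356%. Longer words were CCCACTGTGC, at 99 summits, 15 flanks and 2 GC-matched windows, and CACTGAGAGA, at 113, 5 and 4.

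Several longer words lay mostly on 1 side of the summit. Within 150 bp of a summit, the summit lay upstream of CAGTGTA, on the strand of the word, in 552 cases and downstream in 86, which is 86.5% (exact binomial p 3.5e-84), and the median position of the word was 74 bp downstream of the summit. The summit was likewise upstream of 86.4% of CTCAGTG (median 71 bp) and 76.7% of CAGTGCA (70 bp), each read on its own strand. For CCACTGT, which holds CACTG and not CAGTG on its strand, it was upstream of 86.1% (77 bp), so on the strand that reads CAGTG the summit lay on the opposite side of this word. All occurrences of CAGTG together had the summit upstream in 53.0%. They numbered 183 and 193 in the 20 bp on each side of the summit. At 80 to 100 bp upstream of the summit there were 474, and at 60 to 80 bp downstream 546. Words near 1 summit are not independent, so these p-values are too small.

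**Figure D5:**
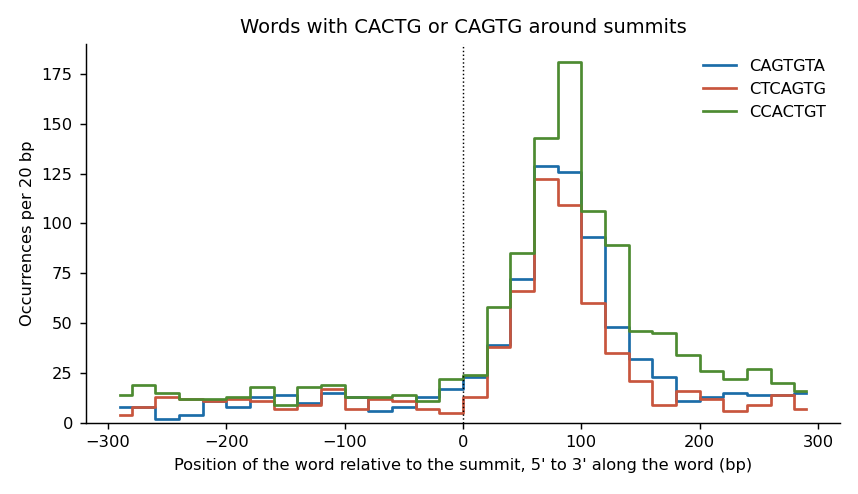
Number of occurrences of CAGTGTA, CTCAGTG and CCACTGT per 20 bp (y axis) by distance from the summit in bp (x axis, each word on its own strand, within 300 bp); CCACTGT holds CAGTG on the opposite strand. CAGTGTA lies downstream of the summit in 86.5% of the cases within 150 bp, at a median of 74 bp.

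Peaks of high signal were more often at promoters. Among the 1250 peaks of highest signal 52.6% of summits were at promoters, and among the 1249 of lowest signal 27.5% (Fisher's exact test, adjusted p 1.3e-36). The Mef2 motif was at 15.3% against 9.21% (adjusted p 3.7e-05) and the homeodomain motif at 19.7% against 15.9% (0.0471). The Gli-type core was at 1.28% of the highest and 3.92% of the lowest (adjusted p 1.5e-04), and Suppressor of Hairless at 1.36% and 3.12% (0.0122). No other motif of the 16 passed. Summit windows of the peaks of highest signal had 34.2% GC, against 35.6% over all summits. These comparisons were not matched on GC content, so base composition may contribute to the motif differences. In replicate 1 alone homeodomain and Suppressor of Hairless did not pass; in replicate 2 alone the Gli-type core did not and M1BP did.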

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

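The test of the Gli-type core away from promoters and coding sequence, and the tests of the CACTG words against shuffled sequence on all summits and away from promoters, were chosen after the results were seen; the other tests in this part were set before their results were known. Peaks outside the 6 main arms were used in no comparison, and they drew attention because any were called there: the conservative set held 14, the wider joint set 45, the replicate 1 set 54 and the replicate 2 set 7. Of these 1, 6, 5 and 0 were on the Y chromosome, and the highest signal among the conservative ones was 547.

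The Gli-type core CCACCCA, named for the family to which lmd belongs, was rarer at summits than in flanks (ratio 0.631). Promoter or coding sequence in the flanks as the whole cause is argued against by the 2299 pairs in which neither the summit nor the flank window touched a promoter, 5′ UTR or coding sequence, where the ratio was 0.638 (95% interval 0.454 to 0.896). Base composition stays a candidate explanation, because against windows of equal GC content the ratio was 1.15 (0.888 to 1.498), an interval that includes 1. Against shuffled sequence the ratio was 2.46, so neither rarity nor excess of this core can be read from the flanks alone. With 1 group, no biological explanation was tested.

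Words with CACTG were frequent within 100 bp of summits, with CACTG itself at 50.4%. The share of CACTG was 50.6% at the 1250 peaks of highest signal and 48.6% at the 1249 of lowest signal. Among the 20 peaks of highest signal, 8 held it. Base composition was tested with 9 words chosen on chromosome 2 and counted on the other arms, where the ratio of the 3237 summit windows to their shuffled copies was 3.34 (95% interval 3.01 to 3.71), which argues against it. Only words holding CACTG were kept, and that core had been noticed over all arms, so the choice did not rest on chromosome 2 alone. Flanks also held CACTG more often than shuffled copies of the summit windows (30.8% against 22.2%). Flanks had 42.4% GC against 35.6% at summits, and GC-matched genomic windows held CACTG in 22.9%. Flanks therefore cannot show how far the ratio is particular to summits. General promoter sequence is argued against by a ratio of 3.88 (3.40 to 4.41) at the 2036 summits on these other arms over 500 bp from a TSS. Annotated mobile elements held the summit of 0.0545% (Wilson 95% interval 0.00962 to 0.308) of the 1835 windows with the words. They held only 0.300% of all summits, although they cover 5.41% of main-arm bases, so a low share was set beforehand. The share shows only that few of these summits lie in annotated elements. Repeats that the annotation does not hold, another factor that precipitates with lmd, and a sample that holds another tagged protein stay open and were not tested. Which protein binds the words may not be read from these lists, and no biological explanation was tested.

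Cytoplasmic ribosomal protein genes held more summits than length-matched lists. Crowded neighbourhoods are argued against, because with lists matched also on the number of other genes with a TSS in the locus 60 genes stood against 25.4 (permutation p 2.0e-04, the smallest possible). Promoters of neighbours are argued against as the whole cause, because 23 genes against 3.77 had a summit within 500 bp of their own TSS and of no other (permutation p 2.0e-04). A candidate explanation that stays open is that strongly transcribed promoters are recovered in precipitations whatever the antibody. The files used here hold neither expression nor control peaks, so it was not tested, and nor was a biological one.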

How the results depend on the processing

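The comparisons with GC-matched windows and, for words, with shuffled sequence, and the IDR level of 0.001, were chosen after the data had been seen. Of the values that answer a comparison, 121 kept their direction and side of the threshold or stayed within their range, 14 moved, 4 reversed and 1 newly passed; of values for single genes, classes, motifs or words these numbers were 850, 152, 13 and 15, and 18 no longer passed. Directions of results that passed neither in the main setting nor in the alternative were not compared. Unless a cause is named, the cause was not tested. The conservative set held 5012 peaks, and the ranked list behind it held 2848 at an IDR of 0.001, fewer by construction. The signal agreement was 0.746 with 50% reciprocal overlap and 0.419 in the ranked lists. The density ratio of the X was 1.14 in the wider joint set. The intron share reversed with the peaks of higher signal (36.5%), at an IDR of 0.001 (37.8%) and with promoters of 1000 bp (34.2%), where promoters take summits from introns by construction, and ranged from 36.6% to 41.5% with 1 replicate left out. The number of lists past the threshold was 1 to 2 with 1 replicate left out, and without replicate 1 the segmentation and Hox list joined. It was 5 under Fisher's exact test without length matching, where the fusion list at 68.2% (adjusted p 0.0064, against 0.124 to 0.983 in its other alternatives), muscle attachment, hedgehog and wnt, and Notch with EGFR and FGF joined the ribosomal list. Motifs rarer at summits numbered 1 against shuffled sequence and 0 against GC-matched windows. Ratios that reversed against shuffled sequence were 2.46 for the Gli-type core, 1.32 for Zic, 1.69 for CCCCCC, 0.856 for GATA, 2.85 for GAGA factor and 0.928 for homeodomain. Those that reversed against GC-matched windows were 1.15, 1.29 and 1.48 for the same first 3, 1.13 for the Twist-type E-box (now past the threshold), 0.961 for GATA and 1.56 for GAGA factor. Away from promoters 4 motifs were more frequent and M1BP reversed (0.778). Of the words tested as k-mers at summits, those more frequent there numbered 495 with 6 bases, for which fewer words exist, 818 against shuffled sequence and 428 against GC-matched windows. Differences between peaks of highest and lowest signal numbered 9 in the wider joint set and 3 to 5 with 1 replicate left out. Read depth is unknown, so how far it limits the weak peaks was not measured.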

Other observations

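The counts at own start sites and the test of mitochondrial ribosomal protein genes were chosen after the results were seen, and the count of unthresholded peaks around lmd was set before its result was known. Beyond the members named by rule, several genes of myoblast fusion had peaks at their own start sites: Abi (signal 141, 50 bp from its TSS) and Vrp1 (191), both regulators of actin branching, and blow (86.1, 227 bp). The blow peak overlapped the replicate 1 set but not the replicate 2 set, and the Vrp1 summit lay within the neighbour mei-S332. A summit lay within 500 bp of an own TSS in 8 of the 22 fusion genes (36.4%) and in 8 of the 21 Notch, EGFR and FGF genes (38.1%), among them the FGF receptor gene htl (222, 384 bp), against 17.2% of all protein-coding genes. Other lists above that share were the ribosomal list (56.5%), glia (30%), heat shock (26.7%), germ line (23.5%) and trachea (23.1%). A summit lay there in 2 of the 31 muscle transcription factor genes, 4 of the 26 sarcomere genes and 0 of the 24 segmentation and Hox genes. These shares were not tested. No summit lay in the loci of the sarcomere genes Mhc, Tm2 and wupA, of the mesodermal regulators tin and nau, or of the fusion gene dock. The fusion gene Crk had none either, but it lies on chromosome 4, where only 2 conservative peaks were called in all. Its lack of a summit therefore says little.

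Strong peaks at mRpL41 and mRpS10 led to the hypothesis that genes of the mitochondrial ribosome hold more summits than other genes of like length. Of 73 such genes, 38 had a summit against 15.6 in matched lists (permutation p 2.0e-04, the smallest possible). The 2 genes that prompted the test were among the 73. Crowded neighbourhoods and promoters of neighbouring genes were not tested for this group, unlike for the cytoplasmic list. The excess therefore remains a hypothesis.

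In the lmd locus, a window of 9492 bp, the unthresholded lists held 18 peaks in replicate 1 and 15 in replicate 2, against means of 8.63 and 6.85 in windows of that length along chromosome 3R. These counts lay at the 99.7 and 98.9 percentiles of 3379 windows, and at 99.8 and 98.8 among windows of genes. A candidate explanation is that the transgene adds copies of the locus to the DNA, which would raise weak signal across it; what genomic sequence the transgene carries is not given in the sources used here. Binding of lmd to its own gene would also place peaks there and was not told apart from it by a test.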
